A study of Homo sapiens with 2 samples.

How the data were processed

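Cells of human milk, taken 2 weeks postpartum, were measured by droplet single-cell RNA sequencing (10x Genomics, 3-prime chemistry) in 2 samples that form 1 group. Per the labels' protocols, cells were pelleted, cryopreserved and thawed, and dye-permeable cells were removed by flow sorting before capture. The labels do not say that the 2 samples came from separate donors. The tests remove differences between the samples, so p-values measure only how far differences between clusters or cell classes vary between them. That spread may be technical, and it is estimated with information shared across genes.

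The deposited matrix holds raw counts of unique molecular identifiers (UMIs), one value per gene and droplet barcode, which the authors aggregated over both libraries. Cell Ranger, Seurat 3.0.1 and the build GRCh38 are named in the submitters' processing notes, and the matrix is marked with software version 3.1.0 per the file headers. Whether reads were subsampled on aggregation, and which annotation was used, is not given in the sources used here. The matrix lists 33694 genes and 6794880 barcodes per library with 9757642 entries above 0, so barcodes had not been filtered to cells. The barcode suffix gives the library. It was not matched to a sample label, and the libraries are called library 1 and library 2. Of the gene identifiers, 32807 were matched to names and 33132 had an entry in GENCODE v29, from which positions on GRCh38 were taken. XIST and Y-linked genes were left out of every table.

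Barcodes were kept as cells with at least 1000 UMIs, at least 500 detected genes and at most 20% mitochondrially encoded UMIs. Scrublet, run per library with an expected rate of 0.05, called 5 of 4241 barcodes doublets (0.118%). These were removed. The called share lies below the expected rate, so barcodes with more than 1 cell can remain among those kept. Library 1 held 17663498 UMIs and library 2 held 21176754, of which 74.5% and 75.2% lay in cells. The kept cells numbered 1751 and 2485. The median cell had 5799 and 4881 UMIs and 1052 and 1013 detected genes.

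Clusters were made with scanpy 1.11.5 and leidenalg 0.10.2 in Python 3.11.15. Counts were scaled to 10000 per cell and log-transformed. From 2000 variable genes scaled within each library, 20 principal components and a graph of 15 neighbours were made, and Leiden clustering was run at resolution 0.5. All cells were clustered first, clusters were named from 15 lists of cell type markers, and the epithelial cells were clustered again. The 613 genes of 22 function lists were left out of clustering, so that they could be compared between clusters. Genes used for clustering are counted apart and are not named as results. A cluster and the genes compared between clusters still come from the same cells, so p-values between clusters are too small to the extent that list genes follow clustering genes. An alternative that clusters on one part of the UMIs and tests on the other was therefore run.

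The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on UMI counts summed per library and cluster, with library as a block, TMM factors, a low-count filter (filterByExpr) and Benjamini-Hochberg adjustment at a threshold of 0.05. Library is a block because each cluster was measured within each library, which is where the pairing comes from. Clusters needed at least 20 cells in each library. The 5 epithelial clusters that had them (E1 to E5, numbered by the lower of their 2 library counts) were fitted together with 4 residual degrees of freedom. E1 and E2 were compared with each other and E3, E4 and E5 each with the mean of the other tested clusters. Each of E3, E4 and E5 is in the mean that the others are set against, so these comparisons are not independent. T-cell-like cells were compared with epithelial cells in a fit with 1 residual degree of freedom. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation. That correlation is estimated from the 4 residual degrees of freedom, or 1 for T-cell-like cells, so the second form has little power. A list that does not pass it is not shown to be unchanged. Lists were also tested with fry, which asks whether the genes of a list move, on balance, one way. Fry does not set the list against other genes.

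For clusters with fewer cells no test was planned. Their UMIs were summed per library and divided by all UMIs outside the 4 genes CSN1S1, CSN2, CSN3 and LALBA. Folds are given for each library, with exact counting intervals where one side had 1 to 3 UMIs. Where one side had 0 UMIs the fold is a bound computed from 3 counts. Intervals are at 95%, by Clopper-Pearson for shares, and cover counting error only.

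The named genes of E1 against E2 were, for each list, up to 2 genes per direction with the largest log2 fold change among those past the threshold with the same direction in both libraries, at most 30 in all. In each other comparison they were the 10 such list genes with the largest change. Some genes that this rule takes are not reported here. Where there was no test, they were the 10 with a fold of at least 2 in each library, at least 20 UMIs on the higher side and the largest smaller fold. CSN1S1, CSN2, CSN3, LALBA, LTF, FASN, XDH, KRT15, KIT, ALDH1A3, CD44, SOX9, KRT14 and EPCAM were followed in every comparison. Samples, tests, lists, named-gene rule and most alternatives were fixed before the data were examined.

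Scripts were tested on simulated counts with 200 changed genes. These counts came from a profile shared by all clusters, with fixed cluster labels and no other difference between clusters. Only genes above a low expected count were changed, so the rates can be better than in the real comparisons. For E1 against E2, with 8433 genes, the test recovered 26.9% of genes changed 1.5-fold, 56.7% changed 2-fold and 84.8% changed 4-fold, and called 2 unchanged genes. For E3 it recovered 17.9%, 61.2% and 86.4%. For T-cell-like cells, with 10939 genes, it recovered 1.49%, 0% and 24.2%, so that comparison has little power.

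Alternatives were other cell filters, mitochondrial limits and doublet treatment, other clusterings (resolution, components, scaling, list genes included), DESeq2 1.42.0 and its size factors, no low-count filter, no replicate block, subtraction of free RNA, cells thinned to 1000 UMIs, each library alone, a fit of E1 and E2 only, and the split of UMIs described above. Library size without a composition factor, fits that include clusters with at least 5 cells per library, and the denominator with milk genes kept were added after seeing the data. Clusters of other settings were matched to E1 to E8 by the greatest overlap of cells, with a Jaccard index of at least 0.25, a limit set after seeing the overlaps. Free RNA was profiled from barcodes with under 50 UMIs. Reference genome sequence was not used here.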

Results

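The study asked which sub-populations of mammary epithelial cells are found in human milk and whether they show progenitor or mature states. Milk cells taken 2 weeks postpartum were profiled in 1 group of 2 libraries, after cryopreservation and a sort that removed dye-permeable cells. The libraries held 17663498 and 21176754 UMIs. They gave 1751 and 2485 cells with a median of 5799 and 4881 UMIs.

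Luminal epithelial-like cells made up 97.1% of cells in library 1 (95% Clopper-Pearson interval 96.3 to 97.9) and 91.7% in library 2 (90.6 to 92.8). T-cell-like cells made up 1.77% (1.21 to 2.50) and 6.92% (5.95 to 7.99), which is 31 and 172 cells. Macrophage-like cells made up 1.09% (0.655 to 1.69) and 1.37% (0.949 to 1.91), which is 19 and 34 cells. In the T-cell-like cluster 9 of 9 T-cell and 4 of 7 NK-cell markers were detected in over 10% of cells. In the macrophage-like cluster 15 of 15 macrophage and 5 of 8 dendritic-cell markers were. These classes may therefore also hold NK and dendritic cells. KRT14, a keratin of basal mammary cells, had 5 and 9 UMIs over all epithelial cells and no cluster was named basal. Cryopreservation and the sort can set these shares, and 1 group allows no test between libraries. MALAT1, a nuclear noncoding RNA, was nearly absent from most epithelial barcodes, as described below. Whether those barcodes hold intact cells was not tested. Mitochondrially encoded UMIs had a median share of 0.279% and 0.292% in epithelial cells, 8.07% and 7.35% in T-cell-like cells, and 6.88% and 7.23% in macrophage-like cells.

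When all cells were clustered, the largest epithelial clusters each held mostly cells of 1 library. In library 1 and library 2 they held 931 and 52, 50 and 826, 51 and 606, 550 and 24, and 2 and 502 cells. The cause was not tested. Clustered again, the epithelial cells fell into 8 clusters, named E1 to E8. E1 to E5 each held at least 62 cells in library 1 and 223 in library 2. Whether each is the same sub-population in both libraries was not tested. E1 held 29.6% (27.4 to 31.8) of epithelial cells in library 1 and 28.3% (26.5 to 30.2) in library 2. E2 held 50.3% (47.9 to 52.7) and 17.9% (16.3 to 19.5), E3 held 7.70% and 9.78%, E4 held 6.06% and 19.4%, and E5 held 3.64% and 18.6%. E6, E7 and E8 held 19, 22 and 5 cells in library 1 and 62, 16 and 58 in library 2. The 4 genes CSN1S1, CSN2, CSN3 and LALBA, which encode caseins and alpha-lactalbumin, took a median of 59.4% and 56.7% of UMIs per cell in E1, 53.6% and 41.6% in E2, and 43.9% and 21.9% in E4. Outside cells, in the free RNA, they took 45.4% and 30.5% of UMIs.

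**Figure D1:**
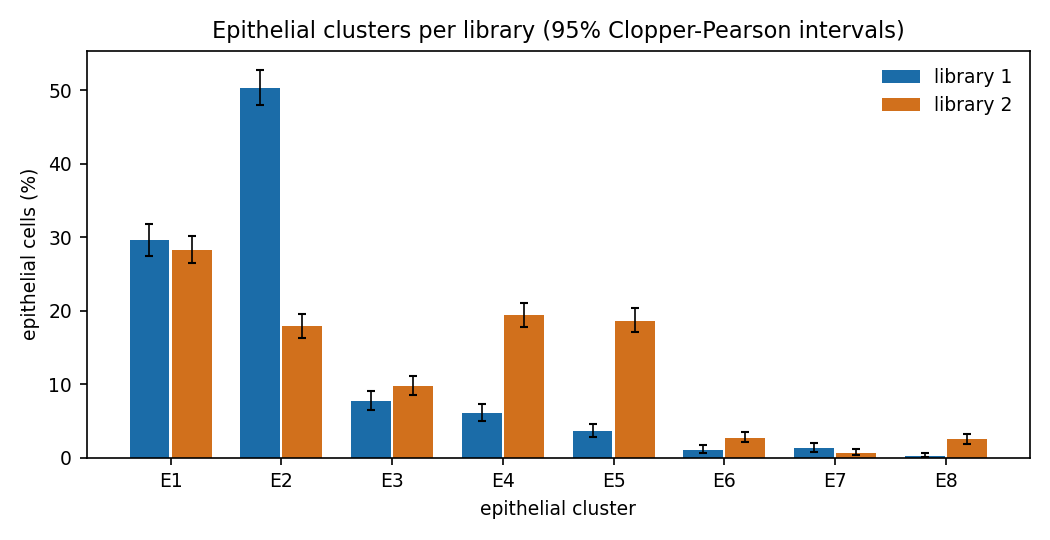
Share of epithelial cells (y axis, %) in each of the 8 epithelial clusters (x axis), with 1 bar per library and 95% Clopper-Pearson intervals, which cover counting error only. E1 held a similar share in both libraries, E2 held 50.3% in library 1 and 17.9% in library 2, and E4 and E5 held larger shares in library 2.

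The first comparison asked how the larger epithelial clusters, E1 and E2, differ in milk synthesis and progenitor genes. In E1, 11 of 12 mitochondrially encoded genes, 16 of 20 milk protein genes, 9 of 28 folding genes, 8 of 20 antigen presentation genes and 7 of 16 lysosomal genes rose. With an estimated correlation the antigen presentation list passed (adjusted p = 0.0443) and the others did not, with an adjusted p = 0.0599, 0.108, 0.0632 and 0.0769 in the order given. MT-ND4, a subunit of respiratory complex I (ENSG00000198886; mitochondrial genome, 10760 to 12137, plus strand), rose in E1 with a log2 fold change of 1.58 (SE 0.18, n = 2 libraries, edgeR adjusted p = 3.05e-07). LYZ, the milk enzyme lysozyme (ENSG00000090382; chromosome 12, 69348341 to 69354234, plus strand), rose by 1.46 (SE 0.26, edgeR adjusted p = 0.00101). JUN, an immediate early transcription factor, fell by 1.76 (SE 0.41, edgeR adjusted p = 0.0114). ATF3, a stress-induced transcription factor, had 2 UMIs in E1 and 39 in E2, a ratio 12.6-fold lower in E1 (interval 3.26 to 108).

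Of 473 list genes tested, 65 were higher and 7 lower in E1, and 13 clustering genes were higher and 24 lower. Of 12 mitochondrially encoded genes, 11 rose and 12 did when adjusted over the list alone (median log2 fold change 1.47, adjusted p = 0.0599 with an estimated correlation). MT-ND5, another complex I subunit, rose by 1.54. Of 20 milk protein genes, 16 rose, and 19 adjusted over the list alone (median 0.73, adjusted p = 0.108 with an estimated correlation). CSN1S1 rose by 0.91, LALBA by 0.82, CSN2 and CSN3 by 0.74 each, LTF, which encodes lactoferrin, by 0.73, and LPO, which encodes lactoperoxidase, by 1.03. Of 28 genes of endoplasmic reticulum folding, 9 rose and 1 fell, and 21 and 1 adjusted over the list alone (adjusted p = 0.0632 with an estimated correlation). SEC61A1, of the translocon, rose by 0.88 and PDIA4, a disulfide isomerase, by 0.82. Of 20 antigen presentation genes, 8 rose, and 13 adjusted over the list alone. This was the 1 list past the threshold with an estimated correlation (adjusted p = 0.0443), and HLA-F rose by 0.82 and HLA-E by 0.71. Of 16 genes of lipid uptake and the lysosome, 7 rose, and 9 adjusted over the list alone (adjusted p = 0.0769 with an estimated correlation). PSAP, the saposin precursor, rose by 0.93 and GPNMB by 1.01. EPCAM, an epithelial adhesion molecule, rose by 0.77.

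In the other lists that passed camera fewer genes were called, and in some of them 0. Of 22 cholesterol synthesis genes, 3 rose, and 5 adjusted over the list alone, among them SC5D (0.99) and DHCR7 (0.69). The list passed camera but had an adjusted p = 0.479 with an estimated correlation. Of 20 genes of mineral and ion transport, 1 rose, CA6 (0.80), a secreted carbonic anhydrase, and 3 adjusted over the list alone (adjusted p = 0.213 with an estimated correlation). Of 13 extracellular matrix genes, 1 rose, TIMP1 (0.80), also adjusted over the list alone (adjusted p = 0.479 with an estimated correlation). Of 83 cytosolic ribosomal protein genes and of 41 nuclear genes of oxidative phosphorylation, 0 passed with edgeR over all genes or adjusted over the list alone, although both lists passed camera upward. Each had an adjusted p = 0.634 with an estimated correlation. Of 19 immediate early and heat shock genes, 1 fell, JUN, and 2 adjusted over the list alone, and the list passed camera downward (adjusted p = 0.201 with an estimated correlation).

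The remaining lists did not pass camera. Of 29 fatty acid and triglyceride genes, 4 rose and 1 fell, and 6 and 2 adjusted over the list alone. DGAT1 rose by 0.65 and ELOVL5 by 0.61, and LPIN1 fell by 1.24. FASN, the fatty acid synthase, had -0.15 (SE 0.17, edgeR adjusted p = 0.769) and XDH, a xanthine dehydrogenase of the milk fat globule, had -0.10 (edgeR adjusted p = 0.853). Of 19 luminal progenitor and stem genes, 1 rose and 2 fell, and 1 and 3 adjusted over the list alone. ITGB1 rose by 0.71, SOX4 fell by 1.43 and EHF by 0.53. KRT15, SOX9, ALDH1A3, CD44 and KIT did not pass, with log2 fold changes of -0.56, -0.52, -0.29, -0.45 and -0.15, the last on 5 UMIs in E1 and 10 in E2. Of 11 lactose synthesis genes, 1 rose, SLC35A2 (0.69), and 2 adjusted over the list alone. Of 14 genes of prolactin and insulin signalling, 1 fell, CEBPB (-0.65), and 3 adjusted over the list alone. Of 13 chemokine and acute phase genes, S100A8 rose by 1.07 and NFKBIA fell by 1.22, and 2 rose and 1 fell adjusted over the list alone. Of 17 genes of involution and cell death, 2 rose, CTSB (0.72) and CTSD (0.63), and 2 rose and 1 fell adjusted over the list alone. The median of this list was -0.09 and its mean -0.05, while camera's direction was upward. Of 7 cell cycle, 17 tight junction, 19 interferon, 17 hypoxia and 16 metallothionein and antioxidant genes, 0 passed with edgeR over all genes or adjusted over the list alone, and the median of the last of these lists was 0.02 while its mean was -0.0022.

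The gene calls depend on the scaling and on the block. In E1 the composition factors were 0.735 and 0.704, and in E2 0.974 and 1.10. With library size alone, the median of all genes moved from -0.01 to -0.53 and the list genes split into 14 higher and 115 lower (10.9% higher, against 90.3%). Of the 11 lists past camera's threshold, 9 kept their direction and side of it. Relative to the median of all genes, milk proteins had 0.74, against 0.75 with the composition factors, and mitochondrially encoded genes 1.47, against 1.48. Camera's direction turned downward for oxidative phosphorylation (adjusted p = 0.00439) and ribosomal proteins (adjusted p = 0.180), although their medians relative to all genes were 0.13 and 0.19, against 0.13 and 0.20 with the composition factors. Without the library block edgeR called 0 list genes (64 at an unadjusted p under 0.05), and at Leiden resolution 1.0 it called 0 (29 at an unadjusted p under 0.05). DESeq2 with the block called 25 higher and 0 lower (101 at an unadjusted p under 0.05). With the 5 called doublets kept edgeR called 15 higher and 1 lower, and with E6 to E8 in the fit 2 higher and 0 lower (72 at an unadjusted p under 0.05). When list genes were used for clustering, the median of the mitochondrially encoded genes was -0.08 and S100A8 had -1.64, but the clusters compared overlapped E1 and E2 with Jaccard indices of only 0.441 and 0.265. Without library 1 the medians of the antigen presentation and ribosomal lists went from 0.56 and 0.18 to 0.37 and 0.12, and LPIN1 had -0.65. GPNMB had 2 UMIs in E2 in library 2, where its ratio was 8.13-fold higher in E1 (1.97 to 71.7). Without library 2 the medians of the cholesterol, extracellular matrix and immediate early lists went from 0.42, 0.36 and -0.37 to 0.11, 0.20 and -0.15.

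**Figure D2:**
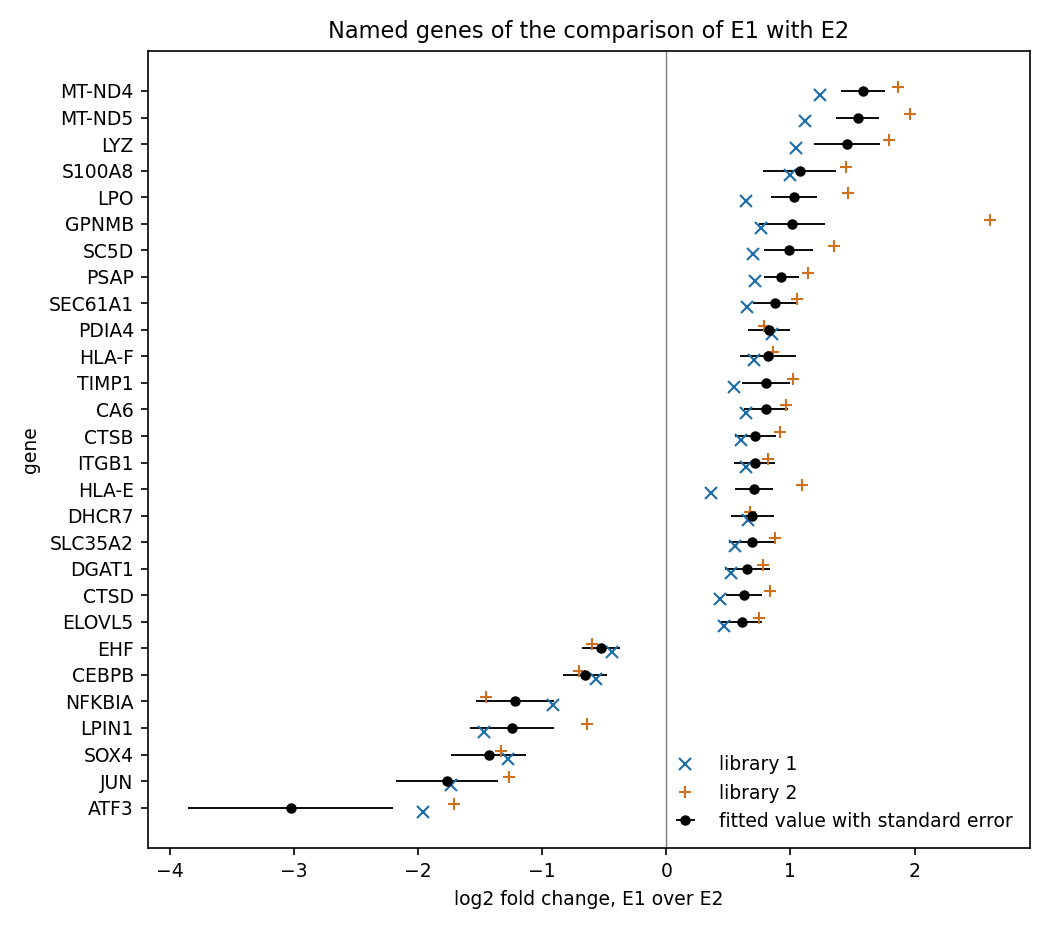
Log2 fold change of E1 over E2 (x axis) for the genes named by the rule (y axis), with the fitted value and its standard error as a black point and line, the value within library 1 as x and within library 2 as +. Every gene shown has the same direction in both libraries, from MT-ND4 at 1.58 down to ATF3, whose 2 UMIs in E1 make its fitted value uncertain.

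The second comparison asked how E3 differs from the mean of E1, E2, E4 and E5. In E3, 10 of 14 genes of prolactin and insulin signalling rose, 74 of 83 ribosomal protein genes and 35 of 41 oxidative phosphorylation genes fell, and of 29 fatty acid genes 11 rose and 4 fell. None of these 4 lists passed with an estimated correlation (adjusted p = 0.248, 0.261, 0.261 and 0.592). MUC4, a membrane mucin (ENSG00000145113; chromosome 3, 195746765 to 195812277, minus strand), rose by 2.05 (SE 0.17, edgeR adjusted p = 1.36e-10). FASN (ENSG00000169710; chromosome 17, 82078333 to 82098332, minus strand) rose by 1.52 (SE 0.12, edgeR adjusted p = 1.36e-10). SCD, a fatty acid desaturase, rose by 1.85 and XDH by 1.36. NOTCH3, a receptor, rose by 2.32 (SE 0.45, edgeR adjusted p = 0.000231) and SOX9, a transcription factor of luminal progenitors, by 1.74 (SE 0.18, edgeR adjusted p = 1.03e-08).

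Of 473 list genes, 90 were higher and 166 lower in E3, and 555 clustering genes were higher and 54 lower. Of 83 ribosomal protein genes, 74 fell, and 1 rose and 75 fell adjusted over the list alone (median -0.66, adjusted p = 0.261 with an estimated correlation). Of 41 oxidative phosphorylation genes, 35 fell, and 38 adjusted over the list alone (median -0.46, adjusted p = 0.261 with an estimated correlation). Of 14 genes of prolactin and insulin signalling, 10 rose and 0 fell with edgeR, as they did adjusted over the list alone (median 0.93, adjusted p = 0.248 with an estimated correlation), among them IRS2, an insulin receptor substrate, with 2.14. Of 19 progenitor genes, 7 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.248 with an estimated correlation). ALDH1A3 rose by 0.87, KRT15 had -0.25 and CD44 had 0.94 (edgeR adjusted p = 0.432 and 0.243). Of 13 extracellular matrix genes, 8 rose, among them TNC, a matrix glycoprotein, with 1.86, and 9 rose and 1 fell adjusted over the list alone (adjusted p = 0.592 with an estimated correlation). Of 29 fatty acid genes, 11 rose and 4 fell over all genes and adjusted over the list alone (adjusted p = 0.592 with an estimated correlation). Of 20 mineral transport genes, 9 rose and 3 fell, and 11 and 4 adjusted over the list alone (adjusted p = 0.592 with an estimated correlation), with SLC39A14 at 1.74. Of 20 antigen presentation genes, 1 rose and 8 fell, and 1 and 9 adjusted over the list alone (adjusted p = 0.248 with an estimated correlation). Of 12 mitochondrially encoded genes, 4 fell, and 5 adjusted over the list alone (adjusted p = 0.694 with an estimated correlation). CSF1, a macrophage growth factor, rose by 2.07, but had 0.56 without library 2. The median of the progenitor list went from 0.83 to 0.32 without library 1 and 0.25 without library 2, that of the fatty acid list from 0.40 to 0.24 without library 1, and that of the matrix list from 0.97 to 0.64 without library 2. The progenitor median was lower with either library left out, which the change from fitted to shrunken values can bring.

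Among milk protein genes 6 rose and 6 fell, and 6 and 7 adjusted over the list alone. The median of this list was -0.12 and its mean was 0.11. Camera's direction was downward for interferon and immediate early genes in E3, with medians of 0.07 and 0.06 and means of 0.20 and 0.03. It was also downward for hypoxia and lysosomal genes, with medians of -0.17 and -0.07 and means of 0.02 and 0.06, and none of these 4 lists passed camera. CSN1S1 fell by 0.68, LALBA by 0.61 and EPCAM by 0.75, while CSN2 had -0.06, CSN3 0.06 and LTF -0.04 and did not pass. CSN2 was positive with the lower and the higher cell filter and with E6 to E8 in the fit. KIT, a receptor of luminal progenitors, had a fitted value of 2.18 (SE 0.81, edgeR adjusted p = 0.0396), but E3 held 0 KIT UMIs in library 1 and 10 in library 2, and without library 2 the value was -1.45. Library 1 held 9 KIT UMIs in the other clusters, so its value shows no direction beyond counting error. S100A10 rose by 1.73 but had -0.76 with the lower cell filter, -0.02 with the UMIs split and -0.13 with E6 to E8 in the fit. With library size alone the median of all genes was 0.46 and the list genes split into 144 higher and 26 lower (84.7% higher, against 35.2%). Of the 9 lists past camera's threshold 7 kept it and 0 changed direction, while antigen presentation (adjusted p = 0.0745) and mitochondrially encoded genes (adjusted p = 0.219) lost it, with medians of -0.49 and -0.35 relative to all genes. Without the block edgeR called 43 list genes higher and 35 lower.

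The third comparison set E4 against the mean of the other tested clusters. In E4, 78 of 83 ribosomal protein genes, 8 of 13 chemokine genes and 10 of 19 immediate early genes rose, and 16 of 20 milk protein genes, 14 of 22 cholesterol genes, 16 of 29 fatty acid genes and 11 of 20 mineral transport genes fell. None of these 7 lists passed with an estimated correlation (adjusted p = 0.267 to 0.279). TM4SF1, a tetraspanin-like surface protein (ENSG00000169908; chromosome 3, 149369022 to 149377865, minus strand), rose by 3.48 (SE 0.22, edgeR adjusted p = 6.77e-14). ANXA1, annexin A1, rose by 3.31 (SE 0.18, edgeR adjusted p = 2.94e-15), S100A10 by 3.42, ATF3 by 3.43 and VIM, the intermediate filament vimentin, by 2.27. KRT15, a keratin of progenitor cells (ENSG00000171346; chromosome 17, 41513743 to 41522529, minus strand), rose by 1.94 (SE 0.18, edgeR adjusted p = 3.92e-10) and CD44, an adhesion receptor, by 1.81 (SE 0.45, edgeR adjusted p = 0.00302). CSN2, beta-casein (ENSG00000135222; chromosome 4, 69955256 to 69961007, minus strand), fell by 1.38 (SE 0.14, edgeR adjusted p = 4.39e-09).

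Of 473 list genes, 149 were higher and 111 lower in E4, and 143 clustering genes were higher and 223 lower. Of 83 ribosomal protein genes, 78 rose, and 79 adjusted over the list alone (median 0.59, adjusted p = 0.267 with an estimated correlation). Of 20 milk protein genes, 1 rose and 16 fell, and 1 and 17 adjusted over the list alone (median -0.83, adjusted p = 0.267 with an estimated correlation). CSN3 fell by 1.14, LALBA by 0.86, CSN1S1 by 0.82 and LPO by 2.77, while LTF had -0.25 and did not pass. Of 22 cholesterol genes, 14 fell, and 19 adjusted over the list alone. Of 29 fatty acid genes, 16 fell, and 20 adjusted over the list alone. FASN fell by 1.10 and XDH by 1.02. Of 28 folding genes, 1 rose and 12 fell, and 1 and 13 adjusted over the list alone. Of 20 mineral transport genes, 11 fell, and 1 rose and 13 fell adjusted over the list alone. These 4 lists had an adjusted p = 0.279 with an estimated correlation. Of 13 chemokine genes, 8 rose, and of 19 immediate early genes, 10 rose and 1 fell, while adjusted over the list alone the counts were 8, 12 and 1. Of 7 cell cycle genes, 3 rose, and 4 adjusted over the list alone, among them CCND1, a cyclin, by 2.12. These 3 lists had an adjusted p = 0.267 with an estimated correlation. Of 41 oxidative phosphorylation genes, 11 rose, also adjusted over the list alone (adjusted p = 0.312 with an estimated correlation). Of 12 mitochondrially encoded genes, 6 fell, and 10 adjusted over the list alone (adjusted p = 0.361 with an estimated correlation), with a median of -0.79 without library 1 and 0.03 without library 2. Of 16 lysosomal genes, 2 rose and 7 fell, and 2 and 8 adjusted over the list alone (adjusted p = 0.297 with an estimated correlation). Of 17 tight junction genes, 2 rose and 6 fell, and 2 and 9 adjusted over the list alone (adjusted p = 0.279 with an estimated correlation). Of 14 genes of prolactin signalling, 1 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.297 with an estimated correlation). Other medians also differed when values came from 1 library. That of the milk protein genes was -1.27 without library 1 and -0.47 without library 2. Without library 2 the cholesterol list went from -1.08 to -0.16, fatty acids from -0.68 to -0.34, mineral transport from -0.84 to -0.39, tight junctions from -0.53 to -0.22, lysosomal genes from -0.63 to -0.38 and prolactin signalling from -0.38 to -0.25. CSN3 had -1.76 without library 1, and KRT15 and LPO had 0.70 and -2.16 without library 2. CCND1 had 2 UMIs in E4 in library 1, a ratio of 1.79 (0.20 to 7.61) to the other clusters together. ATF3 had 2.07 and 2.11 without library 1 and library 2, both below the fitted value, which the change of estimator can bring.

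LAMA3, a laminin chain, fell by 2.42, PDK1, a kinase of pyruvate dehydrogenase, by 2.11 and EPCAM by 0.49. Of 19 progenitor genes, 5 rose and 2 fell, and 6 and 3 adjusted over the list alone, and the list did not pass camera. Of 13 extracellular matrix genes, 3 rose and 2 fell, and 3 and 4 adjusted over the list alone. They had a median of -0.30 and a mean of 0.21, and hypoxia genes a median of 0.20 and a mean of -0.02, with camera's direction upward and neither list past its threshold. SOX9 had -0.29, KIT -0.27 and ALDH1A3 -0.0053, and none of these 3 passed. ALDH1A3 passed upward under 7 alternatives, at 0.41 to 1.13, and downward at Leiden resolution 1.0, at -0.80. With E6 to E8 in the fit, the mean of the other clusters includes cells with few milk transcripts. The median of the milk protein genes was then 0.18, that of the immediate early genes turned negative, VIM had -0.33 and 8 list genes were higher and 12 lower. At Leiden resolution 1.0 VIM, CCND1 and CD44 had -0.33, -0.12 and -1.64. With library size alone the median of all genes was 0.43 and the list genes split into 231 higher and 58 lower (79.9% higher, against 57.3%). Of the 14 lists past camera's threshold 12 kept it and 0 changed direction, while folding (adjusted p = 0.0586) and prolactin signalling (adjusted p = 0.0729) lost it, with medians of -0.35 and -0.39 relative to all genes. Without the block edgeR called 17 list genes higher and 24 lower.

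The fourth comparison set E5 against the mean of the other tested clusters. In E5, 7 of 22 cholesterol genes and 7 of 20 milk protein genes rose, and 2 of 13 chemokine and acute phase genes fell. These 3 lists passed camera but had an adjusted p = 0.429 with an estimated correlation. SQLE, the squalene epoxidase (ENSG00000104549; chromosome 8, 124998497 to 125022283, plus strand), rose by 1.44 (SE 0.25, edgeR adjusted p = 0.000433). MSMO1, of the same pathway, rose by 1.08, LAMA3 by 1.37, LPO by 1.23 and ELOVL5 by 0.93. ANXA1 fell by 2.36 (SE 0.40, edgeR adjusted p = 0.000444), TM4SF1 by 2.16 and SAA1, serum amyloid A, by 2.07 (SE 0.32, edgeR adjusted p = 0.00018). S100A9, a subunit of calprotectin, fell by 0.92. E4 is in the mean that E5 is set against. It held 654 ANXA1 and 363 TM4SF1 UMIs, against 185 and 86 in the other tested clusters together. The falls of these genes in E5 thus also carry the difference of E4.

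Of 473 list genes, 26 were higher and 10 lower in E5, and 47 clustering genes were higher and 29 lower. Of 22 cholesterol genes, 7 rose, and 12 adjusted over the list alone. Of 20 milk protein genes, 7 rose and 1 fell, and 12 and 1 adjusted over the list alone. Of 28 folding genes, 4 rose, and 7 rose and 2 fell adjusted over the list alone. Of 29 fatty acid genes, 3 rose, and 7 adjusted over the list alone. Of 13 chemokine genes, 2 fell, and 4 adjusted over the list alone. Of 83 ribosomal protein genes, 3 fell, and 10 adjusted over the list alone (median -0.21). Of 12 mitochondrially encoded genes, 0 passed with edgeR and 8 fell adjusted over the list alone (median -0.40). These 7 lists had an adjusted p = 0.429 with an estimated correlation. Of 20 mineral transport genes, 1 rose, and 4 adjusted over the list alone (adjusted p = 0.568 with an estimated correlation). CSN2 rose by 0.72, CSN1S1 by 0.55, LALBA by 0.51 and EPCAM by 0.45, while CSN3 (0.48), FASN (0.34), XDH (0.39), LTF (-0.11), ALDH1A3 (-0.13) and SOX9 (-0.58) did not pass. CD44 had 2 UMIs in E5, a ratio 4.52-fold lower (interval 1.21 to 37.97), and KIT had 1, a ratio of 0.285 (interval 0.0070 to 1.71), and neither passed. Prolactin signalling genes had a median of 0.04 and a mean of -0.07, and antigen presentation genes had -0.0086 and -0.05, while camera's direction was upward for both without passing. KRT15 fell by 1.36 (edgeR adjusted p = 0.00429), with 0.04 in library 1 and -1.57 in library 2.

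The cholesterol, fatty acid and mineral transport lists of E5 had medians of 0.73, 0.53 and 0.38 without library 1 and -0.02, -0.0093 and -0.20 without library 2. The other 5 lists that passed camera had the same sign without library 2, with medians of 0.07 for milk proteins, 0.06 for folding, -0.60 for chemokines, -0.17 for ribosomal proteins and -0.59 for mitochondrially encoded genes. Without library 1 milk proteins had 0.65 and mitochondrially encoded genes -0.25. With at most 10% mitochondrial UMIs the median of the mitochondrially encoded genes turned positive. The cluster matched there overlapped E5 with a Jaccard index of only 0.312. LPO and MSMO1 had 0.59 and 0.48 without library 2. ANXA1, TM4SF1 and SAA1 had 0, 0 and 1 UMIs in E5 in library 1, and library 1 alone shows no fall of these genes beyond counting error. Without the block edgeR called 0 list genes (49 at an unadjusted p under 0.05), while DESeq2 with the block called 8 higher and 2 lower. With library size alone the median of all genes was -0.35 and the list genes split into 10 higher and 81 lower (10.99% higher, against 72.2%). Of the 8 lists past camera's threshold 6 kept it and 0 changed direction, while folding (adjusted p = 0.282) and mineral transport (adjusted p = 0.118) lost it, with medians of 0.27 and 0.22 relative to all genes. Fry passed 4 lists in E1 against E2, 7 in E3, 13 in E4 and 0 in E5, where its test of change in either direction gave 4 lists an unadjusted p under 0.05 and camera passed 8.

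T-cell-like cells were compared with all epithelial cells, to describe another cell type of milk. In them 19 of 20 milk protein genes, 22 of 30 fatty acid genes and 16 of 18 tight junction genes fell, and 18 of 27 interferon genes, 16 of 30 immediate early genes and 13 of 13 mitochondrially encoded genes rose. These 6 lists passed camera but had an adjusted p = 0.623 with an estimated correlation. With 1 residual degree of freedom that form could hardly pass any list, so it does not weigh against them. Most epithelial barcodes held little of the nuclear RNA MALAT1 and T-cell-like cells much. How far this difference shapes these lists was not tested. THRSP, a regulator of lipid synthesis, had 0 UMIs in T-cell-like cells and was at least 47.6-fold lower over both libraries, with the floor of 3 counts over the group. TM4SF1 was at least 14.9-fold lower, CXCL2 12.8, ALDH1A3 11.3, ALDH1A1 7.71, TCN1 5.96, SAA1 5.95, OSMR 5.92 and HES1 5.29, all with 0 UMIs. In library 1 alone, with the same floor in that library, the limits were 9.89 for THRSP, 2.29 for CXCL2, 1.49 for ALDH1A1, 1.27 for OSMR and 1.24 for ALDH1A3, and the depth gave none for TM4SF1, SAA1, TCN1 and HES1. In library 2 alone they were 31.4 for THRSP and 3.76 for OSMR. CCL4, a chemokine of immune cells (ENSG00000275302; chromosome 17, 36103590 to 36105621, plus strand), had 218 UMIs in T-cell-like and 3 in epithelial cells, a ratio of 3111 (interval 1051 to 15202). It was 12355 (2170 to 492575) in library 1 and 1570 (425 to 13119) in library 2. CD44 rose by 5.11 (SE 0.54, edgeR adjusted p = 9.11e-20). KRT15 and SOX9 had 3 and 2 UMIs and were 34.5-fold (11.8 to 168) and 10.4-fold (2.86 to 85.8) lower. These UMIs came from library 2, where the ratios were 42.4-fold (14.5 to 206) and 8.78-fold (2.42 to 72.7) lower, and in library 1 they were at least 2.56 and 1.13-fold lower. All these ratios and limits are over all UMIs, milk genes included, without a composition factor. The fitted log2 fold changes, which carry that factor, were -6.73 for KRT15, -4.72 for SOX9 and 10.35 for CCL4.

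Of 552 list genes, 97 were higher and 255 lower in T-cell-like cells, and 1076 clustering genes were higher and 322 lower. Of 20 milk protein genes, 1 rose and 19 fell. CSN1S1 fell by 7.16, CSN2 by 7.08, CSN3 by 7.14, LALBA by 7.11 and LTF by 7.71. FASN and XDH each fell by 5.43 and EPCAM fell by 6.08. Of 30 fatty acid genes 1 rose and 22 fell, of 18 tight junction genes 16 fell, of 41 oxidative phosphorylation genes 38 fell, and of 22 cholesterol genes 13 fell. Of 27 interferon genes 18 rose and 3 fell, of 30 immediate early genes 16 rose and 2 fell, of 21 antigen presentation genes 10 rose and 2 fell, and of 13 mitochondrially encoded genes 13 rose. Of 18 metallothionein and antioxidant genes 10 fell. Adjusted over the list alone, the counts of these lists were equal except for 39 oxidative phosphorylation genes lower, 3 immediate early genes lower and 11 antigen presentation genes higher. Of 30 folding genes 1 rose and 18 fell, of 20 progenitor genes 2 and 14, of 17 lysosomal genes 1 and 10, of 13 lactose genes 1 and 7, and of 83 ribosomal protein genes 2 and 24. Adjusted over the list alone, 21, 15, 11, 7 and 19 fell and the numbers that rose were equal. Camera's direction was upward for cell cycle, extracellular matrix and involution genes, with medians of -0.62, -1.53 and 0.06 and means of -0.83, -2.30 and -0.28, and these did not pass. Camera passed 15 lists, and these had an adjusted p = 0.623 with an estimated correlation except the ribosomal list, with an adjusted p = 0.740 with an estimated correlation, so that 0 passed. Fry passed 2. With library size alone the median of all genes moved from -0.39 to 0.98 and the list genes split into 170 higher and 133 lower (56.1% higher, against 27.6%). Of the 15 lists 13 kept camera's threshold, the lactose list lost it (adjusted p = 0.0564), and the direction of the ribosomal list turned upward without passing (adjusted p = 0.822), with a median relative to all genes of 0.05 in place of -0.10. Without library 1 and library 2, the milk protein list had medians of -5.67 and -8.60, against -6.90, tight junctions -5.34 and -4.89, against -7.01, immediate early genes 0.47 and 1.91, against 1.30, and metallothionein genes -2.70 and -1.23, against -1.89. The tight junction medians were smaller in size without either library, which the change of estimator can bring. Without library 2 interferon genes went from 2.16 to 1.20, fatty acids from -3.67 to -4.33, lactose genes from -2.09 to -3.48 and folding genes from -1.50 to -2.22, and without library 1 progenitor genes from -5.22 to -4.30. CSN1S1, CSN2, CSN3 and LALBA had -5.78, -5.42, -5.79 and -5.66 without library 1 and -8.69, -8.82, -8.75 and -8.61 without library 2. LTF had -6.48 and -9.85 and XDH -4.71 and -6.63 without library 1 and library 2, and FASN had -4.63 without library 1. In library 1 T-cell-like cells had 3 FASN and 1 EPCAM UMIs, ratios 35.5-fold (12.1 to 172) and 38.6-fold (6.93 to 1525) lower. Pooled over T-cell-like cells, the 4 milk genes took 0.493% and 1.89% of UMIs, which would be a free RNA share of 1.09% and 6.19% if all of them were free RNA. The median share of the 4 genes per T-cell-like cell was 0.406% and 0.390%, so that the pooled share of library 2 lies above that of a typical cell.

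E6, E7, E8 and the macrophage-like cells had too few cells in 1 library for the planned test, and their values carry no p. Folds are given for library 1 and library 2. E6 and macrophage-like cells held far more MALAT1, a nuclear RNA, than E1 to E5, as described below. How far this difference shapes their folds was not tested. In E6, of 26 immediate early genes 22 were at least 2-fold higher in both libraries, and of 17 metallothionein and antioxidant genes 8 were higher and 2 lower. MT1G, which binds zinc and copper, was 3552 and 1402-fold higher than in E1 to E5 together, MT1E 1192 and 1002-fold, MT2A 772 and 831-fold, MT1X 1337 and 576-fold, FOS (ENSG00000170345; chromosome 14, 75278774 to 75282230, plus strand) 1722 and 2388-fold and DUSP1, a phosphatase, 603 and 1227-fold. MT1M had 3 UMIs on the lower side in each library and was 1819-fold (614 to 8890) and 5010-fold (1712 to 24317) higher. KLF4 was 589-fold (95.7 to 24272) and 604-fold (204 to 2951) higher, FOSB 2972-fold (523 to 118375) and 699-fold, and CXCL3 2325-fold and 518-fold (89.7 to 20765). Of 41 oxidative phosphorylation genes 23 were lower. Of 18 progenitor genes 7 were higher, with SOX9 4.17 and 5.18-fold and CD44 6.87 and 19.7-fold higher. CSN2 was 4.73 and 6.60-fold lower, and of 20 milk protein genes 12 were lower. E6 cells had a median of 13206 and 17272.5 UMIs, against 5861 and 5124 in all epithelial cells.

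In E7, of 20 milk protein genes 13, of 13 mitochondrially encoded genes 11 and of 29 fatty acid genes 16 were lower. It had no matching cluster under 7 of 11 other choices of cells or clustering, and under 2 more the match held cells of library 1 only. KRT23, a keratin, was at least 840-fold higher in library 1, where E1 to E5 had 0 UMIs, and 399-fold in library 2. VIM was 244 and 84.8-fold higher, ANXA1 83.5 and 23.9-fold, S100A10 35.0 and 27.7-fold, KRT15 17.0 and 8.09-fold, CD44 12.5 and 16.8-fold and ALDH1A3 4.94 and 2.20-fold. KRT14 had 4 and 1 UMIs in E7 and 1 and 8 in E1 to E5, ratios of 206 (20.4 to 10131) and 7.83 (0.176 to 58.4). The median share of the 4 milk genes per cell was 0.267% and 8.02%. CSN2 was 88.6 and 37.3-fold lower, LALBA 59.0 and 9.13-fold, CSN3 51.5 and 4.83-fold, CSN1S1 24.2 and 3.95-fold and LTF 9.79 and 1.45-fold. B4GALT1, a lactose synthase subunit, was 18.4 and 12.9-fold lower and THRSP, with 0 UMIs, at least 22.1 and 13.1-fold. MT-CYB was at least 37.2-fold and 13.8-fold lower. MT-CO3 had 1 UMI in library 1 and was 217-fold lower there (38.9 to 8568). Its fall in library 2 was smaller. With the milk genes kept in the denominator, its ratio to E1 to E5 was 0.0101 in library 1 and 0.121 in library 2. ACLY, with 1 UMI in each library, was 18.8-fold (3.37 to 745) and 25.1-fold (4.50 to 992) lower. The median share of mitochondrially encoded UMIs per cell was 0% and 0.0116%.

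In E8, 4 of 7 cell cycle genes were higher and 11 of 20 milk protein genes were lower. TOP2A, a topoisomerase of dividing cells (ENSG00000131747; chromosome 17, 40388516 to 40417950, minus strand), was 4377-fold (704 to 181031) and 1609-fold (439 to 13395) higher, with 1 and 2 UMIs in E1 to E5. STMN1 was 46.4 and 31.7-fold higher, PCNA 29.4 and 9.11-fold, TUBA1B 8.65 and 6.68-fold and HSP90AA1 2.75 and 3.58-fold. CSN2 was 4.62 and 3.74-fold lower, MUC1 7.62 and 2.76-fold, CEL 2.77 and 3.23-fold, FTL 4.12 and 2.76-fold and CSN3 2.75 and 2.98-fold. Library 1 held 5 of these cells.

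In macrophage-like cells, against all epithelial cells, of 21 antigen presentation genes 16 were higher, of 20 lysosomal genes 13, and of 23 chemokine and acute phase genes 11, with 2 lower. FABP5 was 1888 and 502-fold higher and TIMP2 248 and 170-fold. TREM2, a lipid receptor of macrophages, was at least 184 and 439-fold higher, with 0 UMIs in epithelial cells. MSR1, a scavenger receptor, had 1 epithelial UMI in each library and was 1102-fold (187 to 44617) and 2349-fold (409 to 94012) higher. IL1B, a cytokine, was 606-fold (158 to 5163) higher in library 1 and at least 950-fold in library 2. CCL3 was 1020-fold (172 to 41351) and 1112-fold (297 to 9360) higher and CCL4 854-fold (142 to 34820) and 595-fold (154 to 5092). ZEB2, CCL2 and SLC2A3, with 0 epithelial UMIs in library 1, were at least 560, 505 and 285-fold higher there. Of 21 interferon genes 12 were higher, and of 13 mitochondrially encoded genes 12, while of 20 milk protein genes 17 were lower.

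These counts and folds rest on the denominator. With the milk genes kept in it, every fold was multiplied by 1.77 and 1.65 in library 1 and library 2 for E6, 2.20 and 1.67 for E7, 1.58 and 1.44 for E8, and 2.10 and 1.68 for macrophage-like cells. VIM in E7 was then 537 and 142-fold higher and MT1G in E6 6289 and 2307-fold. Outside the 4 milk genes, 86 list genes were at least 2-fold higher and 72 lower in E6, 11 and 84 in E7, 5 and 24 in E8, and 110 and 121 in macrophage-like cells. With them the counts were 108 and 9, 92 and 53, 8 and 1, and 126 and 64, and 1 oxidative phosphorylation gene was lower in E6 and 1 milk protein gene in E8. In E7 the ribosomal protein genes had 0 of 83 higher outside the milk genes and 64 with them. XDH and EPCAM in E6, LTF, SOX9 and EPCAM in E7, and EPCAM in E8 then changed direction in 1 library.

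MALAT1, a nuclear noncoding RNA (ENSG00000251562; chromosome 11, 65497688 to 65506516, plus strand), was chosen after its values were seen. In E1 to E5 together it had 0.0459 and 0.277 UMIs per 10000 in library 1 and library 2. In T-cell-like cells it had 863 and 843, in macrophage-like cells 336 and 385, in E6 326 and 416, and in E8 7.19 and 32.6. In free RNA it had 41.8 and 52.2.

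**Figure D3:**
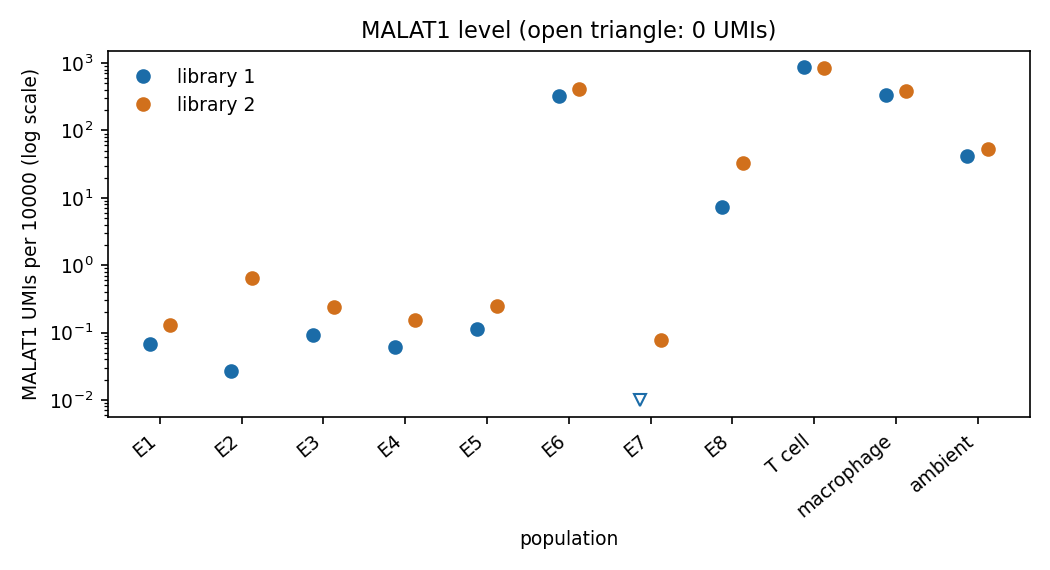
MALAT1 UMIs per 10000 UMIs (y axis, log scale) in each cluster or class and in the free RNA of barcodes with under 50 UMIs, called ambient (x axis), with 1 point per library and an open triangle for 0 UMIs. E1 to E5 and E7 lie below 1, and T-cell-like, macrophage-like and E6 cells lie above 300.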

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

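The test of these barcodes was chosen after the data were seen. Barcodes with at least 200 UMIs that were not kept as cells are outside every comparison. Among them, 387 of 5186 in library 1 and 614 of 4758 in library 2 had under 10% of their UMIs from CSN1S1, CSN2, CSN3 and LALBA, while free RNA had 45.4% and 30.5%. Of these barcodes, 129 and 311 had over 50% mitochondrially encoded UMIs.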

How the results depend on the processing

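The fits without a composition factor, the fits with clusters of at least 5 cells per library, the milk genes in the denominator and the matching of clusters between settings were chosen after seeing the data, as was running the cell filters, mitochondrial limits and doublet treatment on genes, and every setting on lists, in comparisons other than E1 against E2. Of the tested values of named genes under the alternatives, 447 of 794 in E1 against E2 kept their direction and side of the threshold, 318 lost the threshold, 12 gained it, 6 reversed and 11, past it in neither fit, had the other sign. In the same order the numbers were 285 of 366, 34, 13, 8 and 26 in E3, 329 of 411, 35, 9, 18 and 20 in E4, 207 of 289, 61, 14, 0 and 7 in E5, and 354 of 358, 4, 0, 0 and 0 in T-cell-like cells. Each library alone gives values with no test, of which 12 of 82, 12 of 44, 16 of 46, 10 of 46 and 19 of 42 moved by more than the spread between libraries and 0, 1, 0, 1 and 0 reversed. These values are shrunken differences and not fitted, so part or all of the moves can come from the change of estimator. The spread is taken from the difference between the libraries, so it grows as they disagree. These tallies therefore cannot show that the libraries agree. For lists, milk proteins in E5 had medians of 0.65 and 0.07 with each library left out and were still labelled as not moved. Counts are list genes higher and lower, other values are log2 fold changes or list medians, and the cause was not tested unless given. E5 had no match with the UMIs split, the lower cell filter, Leiden 0.25, joint scaling or list genes in clustering, and under 20 cells in library 1 with the higher filter. E3 had no match at Leiden 0.25, and E7 had none with the UMIs split, either cell filter, either mitochondrial limit, Leiden 0.25 or 10 components. These give no value. The lowest Jaccard index of a match was 0.368 for E1, 0.265 for E2, 0.336 for E3, 0.288 for E4 and 0.310 for E5, so that some values compare largely different cells. Depth limits KIT and CD44, with 5 and 8 UMIs in E1, and KRT14, with 1 and 8 in E1 to E5.

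With at least 2000 UMIs and 1000 genes per cell, 2225 cells were kept. Epithelial shares were 96.2% and 88.7% and the T-cell-like share of library 2 was 9.63%. E1 against E2 had 23 and 0, CSN2 in E3 0.42 and ALDH1A3 in E4 0.73. With at least 500 UMIs and 200 genes, E1 against E2 had 16 and 2, and E3 had S100A10 at -0.76 and CSN2 at 0.52. With at most 10% mitochondrial UMIs, epithelial shares were 97.9% and 93.4% and T-cell-like shares 1.15% and 5.60%. E1 against E2 had 15 lower, ALDH1A3 in E4 1.13, oxidative phosphorylation in E4 -0.071 and mitochondrially encoded genes in E5 0.66, where the matched clusters had Jaccard indices of 0.288 with E4 and 0.312 with E5 and the latter held 539 and 666 cells, against 62 and 425. With no mitochondrial limit, the macrophage-like share of library 2 was 1.91%, E1 against E2 had 13 lower and LPIN1 at 0.029, ALDH1A3 in E4 0.92, and E5 had 18 lower and 5 lists past the threshold in place of 8. With called doublets kept, E1 against E2 had 15 and 1 and E5 14 higher.

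At Leiden resolution 0.25, E1 against E2 had 41 higher, and E4 had ALDH1A3 at 1.09 and oxidative phosphorylation at -0.19. At Leiden resolution 1.0, E1 against E2 had 0 and 0 with edgeR (29 list genes at an unadjusted p under 0.05) and CTSD at -0.10. E4 had 69 and 53, with VIM at -0.33, CCND1 at -0.12, CD44 at -1.64 and the chemokine list at a median of 0.032, with its test turned downward but not past the threshold. With joint scaling E1 against E2 had 16 lower. With 10 components, ALDH1A3 in E4 was 0.51 and E5 had 29 lower. With list genes in clustering, E1 against E2 had oxidative phosphorylation at -0.00949, ribosomal proteins at -0.21, mitochondrially encoded genes at -0.080, MT-ND5 at -0.082, LPIN1 at 0.41 and S100A8 at -1.64, E3 had 46 higher and SOX9 in E4 was 0.65. With the UMIs split between clustering and testing, E1 against E2 had 2 lower, E3 had 54 higher and S100A10 at -0.024, and ALDH1A3 in E4 was 1.07.

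With DESeq2, E1 against E2 had 25 and 0 (101 list genes at an unadjusted p under 0.05, against 65 and 7 with edgeR), E4 73 lower and E5 8 and 2. With no low-count filter E5 had 19 lower. With no replicate block, E1 against E2 had 0 and 0 and E5 0 and 0 with edgeR (64 and 49 list genes at an unadjusted p under 0.05), E3 had 43 and 35 with 4 lists past the threshold, and E4 17 and 24. The block moved the T-cell-like counts by less than 1.5 times. With cells thinned to 1000 UMIs, E1 against E2 had 38 and 2 and HLA-F at -0.062, E3 43 and 79 and mitochondrially encoded genes at 0.078, E4 73 lower and E5 12 and 6. With an estimated correlation, camera passed 1 list in E1 against E2 and 0 in E3, E4, E5 and T-cell-like cells. This form has little power at these residual degrees of freedom.

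With library size alone, E1 against E2 had 14 and 115, oxidative phosphorylation at -0.40 and ribosomal proteins at -0.34, both above the median of all genes of -0.53. E3 had 144 and 26, E4 231 and 58 with ALDH1A3 at 0.41, E5 10 and 81, and T-cell-like cells 170 and 133 with ribosomal proteins at 1.03, where all genes had 0.98. This setting shifts every gene of a comparison. With clusters of at least 5 cells per library in the fit, E6 to E8 join the mean that E3 to E5 are set against, which moves those values by construction. E1 against E2 had 2 and 0. E3 had 18 lower, mitochondrially encoded genes at 0.49, S100A10 at -0.13, CSN1S1 at 0.61, CSN2 at 1.67 and LALBA at 0.85. E4 had 8 and 12 with 5 lists past the threshold, milk proteins at 0.18, fatty acids at 0.10, folding at 0.12, immediate early at -0.43, mitochondrially encoded at 0.33, VIM at -0.33, CSN1S1 at 0.32, CSN2 at 0.29, CSN3 at 0.11, LALBA at 0.46, FASN at 0.075 and XDH at 0.015. E5 had 77 and 40 and mitochondrially encoded genes at 0.27. In this setting edgeR calls replace 2-fold counts for the remaining groups, which is another quantity: E6 had 177 and 220, E7 119 higher, E8 54 higher and macrophage-like cells 215 lower. With milk genes in the denominator, E6 had 9 lower, E7 92 and 53, E8 8 and 1, and macrophage-like cells 64 lower.

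With each library left out in turn, KIT in E3 ranged from -1.45 to 2.32, KRT15 in E5 from -1.57 to 0.038, the mitochondrially encoded list in E4 from -0.79 to 0.027, and in E5 the fatty acid list from -0.0093 to 0.53, the cholesterol list from -0.019 to 0.73 and the mineral list from -0.20 to 0.38. The KIT value of -1.45, counted above as a reversal in E3, rests on 0 UMIs in E3 and shows no direction.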

Other observations

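The tests of dilution, of free RNA, also in E4, and macrophages for MRC1, and of shared immune droplets for E6 were chosen after the result was seen, as were all patterns in this part. The tests of nuclear RNA, of barcodes with only free RNA, of overlapping genes and of free RNA in E6 were written before theirs.

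MRC1, the mannose receptor of macrophages (ENSG00000260314; chromosome 10, 17809344 to 17911170, plus strand), was seen in the epithelial clusters. It had 9.74 and 8.81 UMIs per 10000 in E3 and 5.42 and 7.05 in E5, against 1.89 and 2.79 in macrophage-like cells and 0 and 0.147 in T-cell-like cells. In E4 it had 2.52 and 0.759.

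The low MALAT1 level of E1 to E5 was weighed against 3 technical explanations. Dilution by milk transcripts was argued against, because outside the 4 milk genes even the highest cluster, E2 in library 2, had only 0.00132 of the T-cell-like level. Barcodes with only free RNA were argued against, because free RNA held at least 188 times the level of E1 to E5. Little nuclear RNA in these barcodes may account for it: 7 other nuclear noncoding RNAs, relative to 4 cytoplasmic ones, were at 0.0412 and 0.0200 of the T-cell-like ratio. That ratio also depends on which of these RNAs each cell type expresses, and no biological explanation was tested.

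For MRC1 in the epithelial clusters, free RNA was argued against in E3, whose level was 3.54 and 4.85 times that of free RNA. E4 lay below free RNA, at 0.914 and 0.417 of its level, but held 204 and 256 MRC1 UMIs against 0 and 8 in T-cell-like cells, and the lower 95% counting limit of its level over theirs was 7.38 and 2.58, which argues against free RNA that both take up alike. Droplets shared with macrophages were argued against, since TYROBP and FCER1G UMIs per MRC1 UMI were at most 7.22e-05 of the macrophage-like ratio. Reads of an overlapping gene could not be excluded, because 1 other gene, MIR511, is annotated on the same strand. No biological explanation was tested.

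For the high MALAT1 level of E6, droplets shared with immune cells were argued against. The implied immune share would bring 106 and 622 PTPRC UMIs, and 0 and 7 were seen, at most 0.0113 of that number. Free RNA was argued against, since it had 0.128 and 0.126 of the E6 level. No biological explanation was tested.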
